A study of Mus musculus with 26 samples.

How the data were processed

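Heavy-chain B cell receptor repertoires were sequenced from bulk RNA of wild-type mice associated with the skin commensal *Staphylococcus epidermidis*. The 26 libraries comprised skin, spleen and lymph node with 4 biological replicates each and 2 technical libraries per replicate, plus a positive control with 2 technical libraries whose nature the labels do not state. The tissue was taken from the library titles, because the tissue field reads ear skin also for libraries titled spleen or lymph node. Per the labels' protocols, a commercial immune repertoire service reverse-transcribed the RNA with constant-region primers that carry a 10-nucleotide molecular identifier, extended the products with a mix of V gene primers, amplified them and sequenced them in paired reads from framework 2 into the constant region. That design separates IgM, IgD, IgE, IgA, IgG1, IgG3 and IgG2, the last with its subclasses together.

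The deposited tables give, per library, each distinct heavy-chain sequence with its V, J and constant gene, its junction and a whole-number count, called copies here. Per the labels' protocols molecular identifiers were used, but the file headers do not state whether the deposited count is of identifiers or of reads, so copies may still carry amplification differences. The deposited tables also list V mismatches and the aligned V length per sequence, a measurement other than a count; their median aligned length was 144 nucleotides in every library. Per the submitters' processing notes the genome build was mm10. The alignment and gene assignment program is not given in the sources used here. The files held 2095280 sequences and 4007742 copies, with 0 out-of-frame junctions and 0 stop codons, so no filter on functional sequences was applied or varied.

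The copies of the 2 technical libraries of a biological replicate were added together. A clonotype was a V gene, J gene and junction nucleotide sequence. A lineage, used as an alternative, grouped clonotypes of 1 replicate with the same V gene, J gene and CDR3 length by single linkage at 85% or more identical CDR3 nucleotides. Isotype and class-switched shares were shares of copies. Distinct clonotypes and the share of the 10 largest clonotypes were means over 100 draws of 4976 copies, the total of the smallest skin replicate. V-segment mutation was the mismatched share of aligned V nucleotides, averaged over clonotypes. CDR3 length, V family and J gene shares were also computed per clonotype, with families of at least 1% of clonotypes tested.

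Skin libraries held 2215 to 4183 copies each, spleen libraries 79235 to 683759, lymph node libraries 44772 to 117512 and control libraries 318201 to 327365. A count of 0 among the copies of a skin replicate allows a share of up to 0.0400% to 0.0603%, from a floor of 3 copies over the total. This takes copies as independent draws, but skin clonotypes held 15.3 to 23.4 copies each on average, so these limits may be too low. Such limits, and the exact Clopper-Pearson 95% intervals given for shares of clonotypes, cover counting error only.

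Single values per replicate were compared with exact two-sided permutation tests of the difference of means over the 70 splits of 4 against 4 (smallest possible p = 0.0286), with Benjamini-Hochberg adjustment over the 3 tissue comparisons of a measure, or over the isotypes, families or J genes of a comparison. V gene usage was tested on the number of clonotypes per V gene with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), all 12 tissue samples in the fit, TMM scaling (factors 0.838 to 1.48), edgeR's filter for low counts and Benjamini-Hochberg adjustment over the 91 V genes tested. DESeq2 1.42.0, without edgeR's filter and with its own scaling, was an alternative. Sharing of clonotypes between tissues was tested by an exact one-sided permutation of the replicate numbers of 1 tissue over the 24 pairings (smallest possible p = 0.0417). Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. On simulated counts for 91 V genes with 20 changed 4-fold, the edgeR step recovered 80.0% for skin against spleen with 5 false calls, 65.0% for skin against lymph node with 0 false calls and 100% for spleen against lymph node with 1 false call.

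The tests of tissue comparisons, their alternatives and the rule for named items were fixed before the data were examined. Alternatives on IgA clonotypes, on clonotypes without IgA copies, on nucleotide definitions of public clonotypes and on shares below the limit of a count of 0 were added later, as were tests of explanations where the closing paragraphs say so. All isotypes, J genes and V families were given. V genes were named when their adjusted p was under 0.05, up to 10 in each direction for the skin comparisons and up to 5 for spleen against lymph node, by size of the log2 fold change. Clonotypes named were the 3 largest of each skin replicate found in both technical libraries, and the 3 largest shared with the lymph node of the same number, summarised where they repeat. The V gene lists were B-1 cell and natural antibody genes (IGHV11-1, IGHV11-2, IGHV12-3, IGHV7-1, IGHV7-3, IGHV6-3), the J558 family (IGHV1), the IGHV5 family and the Q52 family (IGHV2). Gene coordinates are those of the RefSeq annotation of GRCm38.p6, the assembly also called mm10. Of 188 V gene names in the files 119 matched a RefSeq symbol, among them 88 of the 91 V genes tested. V genes of 1 family are near-identical in part, so that an assignment can move between neighbours.

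The labels number the biological replicates of each tissue 1 to 4 but do not state that a number is 1 mouse, nor that replicates are separate animals, and p-values then measure the spread between these samples. The alternatives were the amino acid or lineage definition of a clonotype, leaving out single-copy clonotypes, each technical library alone, copies as weights, IgM or class-switched clonotypes alone, other drawing depths, no TMM scaling, no filter on rare V genes, only the 8 samples of the compared tissues, leaving out each replicate, leaving out clonotypes found in the positive control, and the replicate number as a block. The positive control entered no test.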

Results

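Heavy-chain transcripts were counted in skin, spleen and lymph node of wild-type mice associated with *Staphylococcus epidermidis*, a bacterium of normal skin flora, in a series concerned with germinal centre reactions in skin. Each tissue had 4 biological replicates, numbered 1 to 4. All animals were associated, so the comparisons were between tissues. Skin replicates held 4976 to 7495 copies in 275 to 350 clonotypes, spleen replicates 162168 to 1362176 copies in 25645 to 438995 clonotypes, and lymph node replicates 93191 to 228065 copies in 27520 to 117561 clonotypes. The positive control held 645566 copies in 386982 clonotypes. Skin clonotypes had 15.3 to 23.4 copies each on average, against 2.04 to 6.32 in spleen and 1.94 to 3.39 in lymph node.

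IgA was the largest class by copies in 3 of 4 skin replicates, and in skin replicate 1 IgM was larger (44.7% against 41.6%). IgA, the class secreted at mucosal surfaces, made up 57.7% ± 12.7 of skin copies (SD, n = 4), 31.3% ± 2.83 of spleen copies and 2.34% ± 1.98 of lymph node copies. IgM, the class of naive B cells, ran the other way with 32.4% ± 11.3 in skin, 51.5% ± 8.17 in spleen and 72.4% ± 4.64 in lymph node. IgD held 9.68% ± 2.79, 9.70% ± 4.33 and 13.7% ± 1.56. The constant gene Igha lies on chromosome 12 at 113256204 to 113260236 (GRCm38), at the far end of the constant region from Ighm at 113418826 to 113422730.

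By copies, IgG was almost missing from skin. IgG2 made up 0.206% ± 0.362 of skin copies, 5.83% ± 3.14 of spleen copies and 10.3% ± 3.63 of lymph node copies (SD, n = 4). In all skin replicates together 60 of 23462 copies were IgG2, where 2406 would be counted at the mean lymph node share and 1367 at the mean spleen share. Of the 60 copies, 56 were in skin replicate 2. Counted once per clonotype, at unequal depth, IgG2 made up 0.756% ± 0.960 of skin, 2.39% ± 1.60 of spleen and 1.68% ± 0.404 of lymph node clonotypes. By that count skin did not differ from spleen (exact permutation p = 0.171) or from lymph node (exact permutation p = 0.114). IgG1 had 1 copy in skin, against a mean share of 1.02% ± 1.60 in spleen (3.41% in replicate 1, 0.214% to 0.230% in the others) and 0.921% ± 0.564 in lymph node. IgG3 and IgE had 0 of 23462 skin copies, which allows a share of up to 0.0128% if copies are independent draws. These copies fell in only 1267 clonotypes, so that limit may be too low. IgG3 reached 0.462% ± 0.217 in spleen and 0.187% ± 0.129 in lymph node. IgE averaged 0.192% ± 0.369 in spleen and 0.118% ± 0.162 in lymph node, but exceeded the highest limit of a skin replicate, 0.0603%, in only 1 of 4 spleens and 2 of 4 lymph nodes, so that its lower level in skin was not detectable at this depth against the other replicates.

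In exact two-sided permutation tests, IgA was higher in skin than in spleen, and IgG1, IgG2 and IgG3 lower (each p = 0.0286, adjusted p = 0.0400, n = 4 against 4). Against lymph node, IgA was higher in skin and IgM, IgG1 and IgG2 lower (exact permutation p = 0.0286, adjusted p = 0.0333, n = 4 against 4). IgE against both tissues, and IgG3 against lymph node, had the same p, but from skin zeros whose limits overlap the other tissue, and no difference is claimed for them. With every share below 0.0603% set to that limit, an alternative added after the data were seen, IgA, IgG1 and IgG2 in both skin comparisons, IgG3 against spleen and IgM against lymph node kept p = 0.0286, the smallest possible in the exact permutation test. Their adjusted p was then 0.05, not under the threshold, and the counts of isotypes past the threshold, 5 against spleen and 6 against lymph node, both became 0. Both counts also became 0 with each clonotype counted once and without any 1 of the skin replicates, and the count against spleen without any 1 of the spleen replicates or without single-copy clonotypes. By copies, every skin value of IgA, IgG1 and IgG2 lay outside the spleen and lymph node ranges. The losses on leaving out a replicate therefore do not show overlap for these 3 isotypes. With the replicate number as a block, IgG3 passed against spleen, while IgA, IgG1 and IgG2 did not (exact permutation, each adjusted p = 0.320). That test permutes all 3 tissue labels within a number, so values of the third tissue also enter it. Each of these 4 isotypes had the same direction in 4 of 4 numbers, so passing or failing there does not measure paired differences of skin and spleen. Against lymph node IgA, IgM and IgG2 passed with the block and IgG1 did not (exact permutation, adjusted p = 0.341).

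IgM in skin against spleen had an adjusted p of 0.0667 in the exact permutation test. Between spleen and lymph node 0 of 7 isotypes passed. The exact permutation test there gave p = 0.0286 and an adjusted p of 0.100 for IgA (31.3% against 2.34%) and for IgM. Counted once per clonotype, IgA made up 25.6% ± 8.09 of skin, 7.86% ± 3.64 of spleen and 0.550% ± 0.179 of lymph node clonotypes, and IgM 57.4% ± 6.76 of skin clonotypes.

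**Figure D1:**
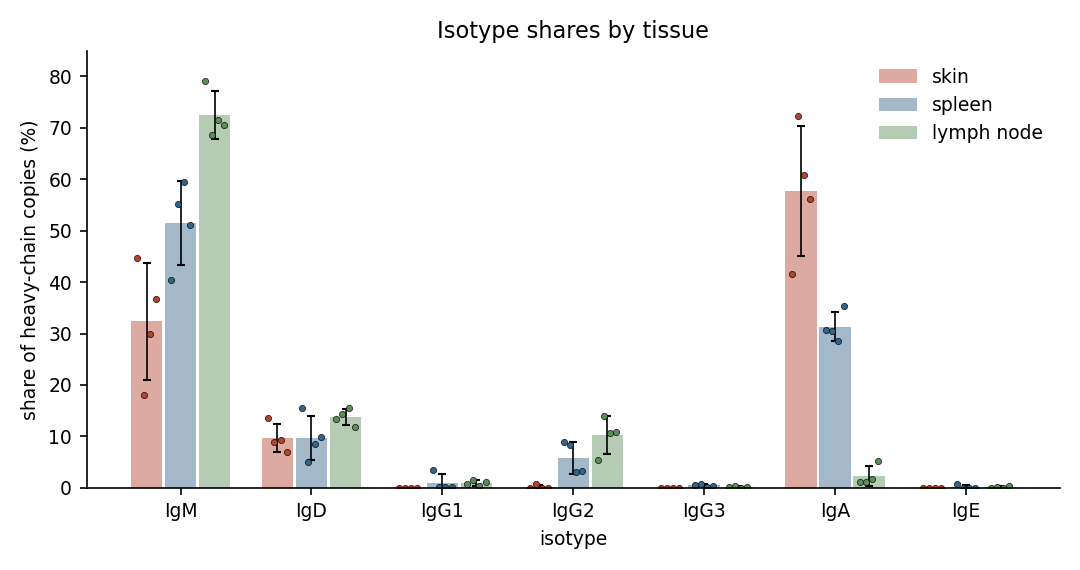
Share of heavy-chain copies (%) per isotype in skin, spleen and lymph node. Bars are means, error bars 1 SD and points the 4 biological replicates of each tissue. IgA averaged 57.7% in skin, 31.3% in spleen and 2.34% in lymph node, and IgG2 averaged 0.206%, 5.83% and 10.3%.

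Class-switched transcripts (IgG, IgA or IgE together) made up 58.0% ± 12.9 of copies in skin, 38.8% ± 5.0 in spleen and 13.8% ± 4.73 in lymph node (SD, n = 4). Both skin and spleen exceeded lymph node (exact permutation p = 0.0286, adjusted p = 0.0429). Skin exceeded spleen by 19.2 percentage points, which missed the threshold (exact permutation p = 0.0571, adjusted p = 0.0571) and passed it without skin replicate 1, at 24.6 points (exact permutation, adjusted p = 0.0286).

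A few clonotypes filled much of the skin repertoire. At 4976 copies drawn, skin held 294 ± 41.7 distinct clonotypes, spleen 3495 ± 308 and lymph node 3856 ± 388 (SD, n = 4). The 10 largest clonotypes took 52.7% ± 12.1 of skin copies, 8.40% ± 2.71 of spleen copies and 11.3% ± 7.67 of lymph node copies. Skin differed from spleen and from lymph node in both measures (each exact permutation p = 0.0286, adjusted p = 0.0429). Spleen against lymph node did not pass (exact permutation p = 0.200 for distinct clonotypes and 0.600 for the 10 largest). The tissue input behind each library is not given in the sources used here, and equal copies do not make equal numbers of cells.

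Skin heavy chains carried more V-segment mutations than those of lymph node. Mismatches covered 1.61% ± 0.485 of V nucleotides per skin clonotype, 0.844% ± 0.214 per spleen clonotype and 0.548% ± 0.0568 per lymph node clonotype (SD, n = 4). Skin and spleen each exceeded lymph node (exact permutation p = 0.0286, adjusted p = 0.0429), while skin against spleen missed the threshold (exact permutation p = 0.0571, adjusted p = 0.0571). Among IgM clonotypes alone, mutation was 0.837% ± 0.0954 in skin, 0.587% ± 0.0941 in spleen and 0.497% ± 0.0476 in lymph node, and skin exceeded spleen (exact permutation p = 0.0286, adjusted p = 0.0429). Among IgA clonotypes alone, a comparison added after the data were seen, mutation was 3.47% ± 0.830 in skin, 3.17% ± 0.180 in spleen and 2.35% ± 0.241 in lymph node. Without skin replicate 1 the difference of all clonotypes between skin and spleen passed at 0.984 points (exact permutation, adjusted p = 0.0286). Without any 1 of the lymph node replicates, neither difference from lymph node passed (exact permutation, adjusted p = 0.0857). All skin and spleen values (lowest 0.955% and 0.682%) still lay above all lymph node values (highest 0.599%). The loss at 4 against 3 therefore does not show overlap.

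**Figure D2:**
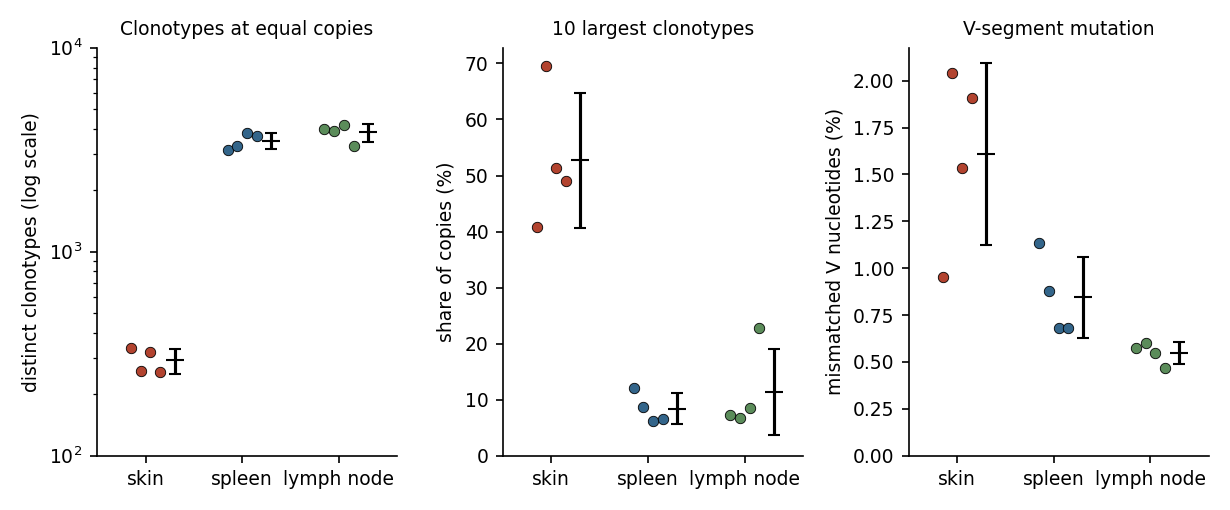
Left, distinct clonotypes among 4976 copies drawn (log axis); middle, share of copies (%) in the 10 largest clonotypes; right, mismatched V nucleotides (%). Points are the 4 biological replicates of skin, spleen and lymph node, and the bar beside them is the mean with 1 SD. Skin lay at 294 clonotypes on average, spleen at 3495 and lymph node at 3856.

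For CDR3 length, V families and J genes 0 comparisons of skin passed in the main setting. Mean CDR3 length was 12.1 ± 0.241 amino acids in skin, 12.0 ± 0.0708 in spleen and 12.3 ± 0.0547 in lymph node (SD, n = 4), and 0 of 3 comparisons passed (lowest adjusted p = 0.0857, spleen against lymph node, exact permutation). Skin minus lymph node was -0.355 amino acids without single-copy clonotypes and -0.556 with copies as weights, and spleen minus lymph node -0.417 and -0.294 (exact permutation, each adjusted p = 0.0429). IGHV1, the J558 family, took 64.2% ± 6.62 of skin, 64.3% ± 4.83 of spleen and 63.2% ± 0.760 of lymph node clonotypes. IGHV5 followed with 8.32%, 8.04% and 8.00%, and IGHV9 with 5.70%, 5.50% and 5.38%. IGHV2 held 3.93%, 4.02% and 5.19%, IGHV3 3.94%, 2.94% and 4.48%, IGHV6 2.84%, 2.92% and 3.14%, IGHV7 1.46%, 1.48% and 1.52%, IGHV8 3.4%, 3.30% and 3.35%, and IGHV10 2.05%, 1.62% and 3.02%. IGHV14 held 3.0% ± 1.15, 5.59% ± 2.54 and 2.26% ± 0.232. For 0 of the 10 families did any tissue comparison pass, and the lowest adjusted p in an exact permutation test was 0.143, for IGHV3 and IGHV14 in spleen against lymph node (unadjusted p = 0.0286).

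J gene use separated spleen from lymph node. IGHJ3 took 14.0% ± 2.72 of spleen and 8.18% ± 0.423 of lymph node clonotypes, IGHJ4 32.0% ± 2.70 and 39.4% ± 1.70, IGHJ1 20.7% ± 0.537 and 19.6% ± 0.313, and IGHJ2 33.3% ± 0.711 and 32.9% ± 1.03 (SD, n = 4). IGHJ1, IGHJ3 and IGHJ4 passed (exact permutation p = 0.0286, adjusted p = 0.0381). Skin lay at 19.1% ± 4.59 for IGHJ1, 30.1% ± 4.21 for IGHJ2, 12.5% ± 1.22 for IGHJ3 and 38.4% ± 3.21 for IGHJ4, and 0 J genes passed against either tissue; the exact permutation test gave p = 0.0286 and an adjusted p of 0.114 for IGHJ3 against lymph node. The 3 calls between spleen and lymph node became 0 without spleen replicate 1, without any 1 of the lymph node replicates, and with copies as weights. With the replicate number as a block IGHJ1 did not pass (exact permutation, adjusted p = 0.693), while IGHJ3 and IGHJ4 did. Skin values also enter that test, and IGHJ1 was higher in spleen in 4 of 4 numbers.

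Single V genes differed between skin and spleen in 7 of 91 tests. IGHV1-7 (2.22% ± 2.42 of skin against 0.480% ± 0.241 of spleen clonotypes), IGHV5-6 (3.11% ± 2.44 against 0.929% ± 0.316), IGHV1-42 (2.36% ± 0.292 against 1.02% ± 0.178) and IGHV1-19 (3.11% ± 1.08 against 1.38% ± 0.189) were higher in skin (SD, n = 4). IGHV1-75 (0.688% ± 0.327 against 2.15% ± 0.435), IGHV1-76 (0.773% ± 0.472 against 2.22% ± 0.212) and IGHV1-80 (1.26% ± 0.390 against 3.52% ± 0.459) were lower. The 3 lower genes lie at the end of the V cluster far from the constant genes on chromosome 12 (GRCm38), at 115833950 to 115834243 for Ighv1-75, 115847881 to 115848174 for Ighv1-76 and 115912344 to 115912637 for Ighv1-80. Ighv5-6 (113625508 to 113625801) lies near the other end, and Ighv1-7 (114538495 to 114538788), Ighv1-19 (114708648 to 114708941) and Ighv1-42 (114937154 to 114937544) lie between; all are annotated as V segments.

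In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, log2 fold changes of skin over spleen were 2.17 (SE 0.602, adjusted p = 0.0377) for IGHV1-7, 1.66 (SE 0.479, adjusted p = 0.0397) for IGHV5-6 and -1.61 (SE 0.304, adjusted p = 0.00621) for IGHV1-80. These counts are small, with 29 skin clonotypes of IGHV1-7 and 9 of IGHV1-75 over the 4 replicates. The skin values of IGHV1-7 and IGHV5-6 overlapped those of spleen, and both calls ended without skin replicate 2 (log2 0.87 and 0.82; adjusted p = 0.474 and 0.253) and with lineages (log2 0.78 and 1.03; adjusted p = 0.687 and 0.157), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In skin replicate 2 large clonotypes used these genes, with CDR3 AKYYSSWFAY for IGHV1-7 (23.8% of copies) and ARRTAMDY for IGHV5-6 (17.7%). Near-variants of both, such as AKCYSSWFAY and AGRTAMDY, counted there as separate clonotypes. The calls of IGHV1-42 and IGHV1-19 were no firmer, kept in 4 and 6 of 19 alternatives, with log2 fold changes down to 0.42 and 0.43. DESeq2 called 48 V genes, 44 higher and 4 lower, against 4 higher and 3 lower with edgeR. The 2 fits differ in filter and scaling, so these counts are not of like fits. A fit of the 8 skin and spleen samples alone called 0 V genes in edgeR, with 16 at an unadjusted p under 0.05. The count was 4 without skin replicate 1 or without spleen replicate 1, 2 without spleen replicate 3, and 11 without skin replicate 2 or without spleen replicate 4.

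Between skin and lymph node edgeR called 0 of 91 V genes, with 17 at an unadjusted p under 0.05, while DESeq2 called 37, all higher in skin. The median log2 fold change in edgeR was -0.0898 in the J558 family, -0.444 in the IGHV5 family, -0.199 in the Q52 family and 0.142 in the B-1 list. The DESeq2 count, from a fit without edgeR's filter and with its own scaling, is therefore not read as a general rise in skin. The V genes with the smallest p were IGHV1-80 (1.26% ± 0.390 of skin against 2.81% ± 0.205 of lymph node clonotypes), IGHV1-78 (0.227% ± 0.152 against 0.979% ± 0.0460), IGHV1-18 (2.01% ± 1.08 against 4.01% ± 0.490) and IGHV1-39 (0.473% ± 0.307 against 1.48% ± 0.0900), each with an adjusted p of 0.0578 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The edgeR count became 1 without skin replicate 1 or 4, 4 without skin replicate 2, and 6 without skin replicate 3.

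Between spleen and lymph node 20 V genes differed, 7 higher and 13 lower in spleen. IGHV14-1 (0.429% ± 0.268 of spleen against 0.101% ± 0.0145 of lymph node clonotypes), IGHV14-3 (2.43% ± 1.08 against 0.789% ± 0.113), IGHV5-9 (0.822% ± 0.0864 against 0.350% ± 0.0208), IGHV14-2 (0.997% ± 0.628 against 0.447% ± 0.0744) and IGHV1-76 (2.22% ± 0.212 against 1.18% ± 0.0650) were higher in spleen. IGHV3-1, IGHV13-2, IGHV3-8, IGHV3-3 and IGHV1-7 were lower, among them IGHV3-8 with 0.156% ± 0.0499 against 0.533% ± 0.0436 and IGHV1-7 with 0.480% ± 0.241 against 1.37% ± 0.161 (SD, n = 4). The log2 fold change of spleen over lymph node was 2.13 (SE 0.572, adjusted p = 0.0171) for IGHV14-1 and -1.76 (SE 0.296, adjusted p = 0.000857) for IGHV3-8, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. DESeq2 called 34 V genes (12 higher, 22 lower), 19 of them among the 20. With copies per V gene in place of clonotypes edgeR called 0, with 5 at an unadjusted p under 0.05. The count was 31 without spleen replicate 2, 8 without spleen replicate 3, and 10, 9, 7 and 6 without lymph node replicates 1, 2, 3 and 4.

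Of the lists fixed in advance, the J558 family had 47 members tested. Between skin and spleen 3 were higher in skin (IGHV1-19, IGHV1-42, IGHV1-7), 3 lower and 41 did not pass, and 6 passed when adjusted over the list alone. Between skin and lymph node 0 passed over all V genes and 4 adjusted over the list alone. Between spleen and lymph node 2 were higher in spleen and 6 lower (such as IGHV1-39, at 0.519% against 1.48%), with 4 adjusted over the list alone. Of 9 members of the IGHV5 family, IGHV5-6 was higher in skin than in spleen (1 adjusted over the list alone), 0 differed between skin and lymph node (0 adjusted over the list alone), and in spleen against lymph node IGHV5-9 was higher and IGHV5-16 lower (2 adjusted over the list alone). Of 7 members of the Q52 family 0 passed in any comparison, also adjusted over the list alone. Of 5 tested B-1 and natural antibody genes 0 passed in any comparison, but 1 passed for skin against spleen when adjusted over the list alone, IGHV11-2 with 0.520% ± 0.488 of skin and 0.104% ± 0.0435 of spleen clonotypes. The whole B-1 list took 4.44% ± 1.73 of skin, 3.65% ± 1.5 of spleen and 3.55% ± 0.206 of lymph node clonotypes (lowest exact permutation p = 0.343, adjusted p = 0.80).

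Skin clonotypes recurred in the spleen of the same replicate number. Of the clonotypes of skin replicates 1 to 4, 4.57% (95% interval 2.64 to 7.32, exact Clopper-Pearson), 17.8% (13.8 to 22.5), 11.2% (7.95 to 15.1) and 15.6% (11.6 to 20.5) were found in the spleen of their own number, on average 12.3% ± 5.85 (SD, n = 4). In spleens of other numbers the mean was 1.23% and the highest value 4.0%, for skin replicate 1 in spleen replicate 2. In the positive control 1.07% of skin clonotypes were found. The own number ranked highest in 4 of 4 skin replicates, and the difference of 11.1 percentage points had the smallest p that the 24 pairings allow (exact one-sided permutation p = 0.0417). For lymph node the shares were 2.6% ± 1.60 in the same number and 0.851% in others, a difference of 1.75 points (exact one-sided permutation p = 0.0417, n = 4), which was 0.968 without replicate 2. By share of copies the same-number excess was 14.4 points (exact one-sided permutation p = 0.0417), but skin replicate 1 had more in lymph node 3 (1.77%) than in its own (1.49%), skin replicate 4 more in lymph node 1 (5.75%) than in its own (5.32%), and skin replicate 2 had 52.9% in its own and 24.3% in lymph node 4. A share of copies counts a skin clonotype in full from 1 copy in the other tissue. AKYYSSWFAY, 23.8% of skin replicate 2, had at most 1 copy in a lymph node of another number. Lymph node clonotypes were found in the spleen of the same number at 2.99% ± 1.71 against 0.779% in other numbers, a difference of 2.21 points (exact one-sided permutation p = 0.0417, n = 4), with the own number highest in 3 of 4. With lineages in place of clonotypes skin and spleen differed by 8.90 points (exact one-sided permutation p = 0.0417), but skin replicate 1 was lowest in its own spleen (22.9%, against 48.3% to 59.0% in the others), and the lymph node differences were 1.53 points for skin (exact one-sided permutation p = 0.125) and 0.182 points for spleen (exact one-sided permutation p = 0.458). Spleen replicate 1 held the fewest clonotypes of the spleens (25645), and these shares were not corrected for depth.

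**Figure D3:**
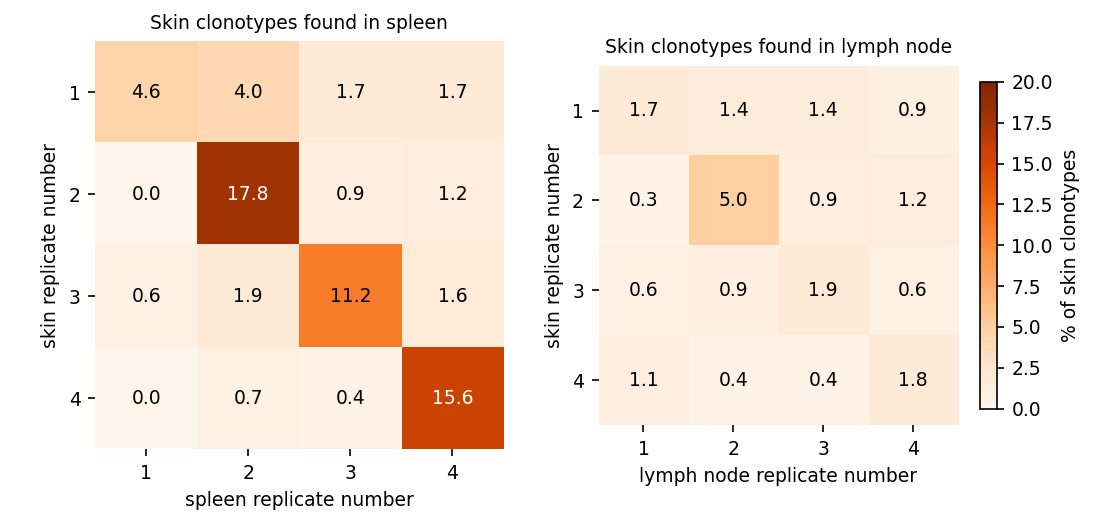
Percent of the clonotypes of each skin replicate (vertical axis) found in each spleen (left) or lymph node (right) replicate (horizontal axis), with the colour scale in percent. The cells of equal numbers hold 4.57% to 17.8% for spleen and 1.71% to 5.0% for lymph node.

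Most of the shared clonotypes were IgA. Of the 152 found in the spleen of the same number 108 were mostly IgA and 44 mostly of another isotype, and 38 had 1 copy in skin. Of 315 skin clonotypes that were mostly IgA 34.3% were found in the spleen of the same number, against 4.62% of other skin clonotypes. These counts take near-variants of a large clonotype as separate. In replicate 2, IGHV1-7 IGHJ3 AKYYSSWFAY came with AKCYSSWFAY, AKHYSSWFAY and AKYYSPWFAY, each with 2 to 3 skin copies and 1 spleen copy. The shared clones may therefore be fewer than the shared clonotypes. The 152 shared clonotypes held 56.2% ± 18.0 of skin copies and 87.8% ± 11.2 of skin IgA copies (SD, n = 4). Their V mutation was 2.98% ± 0.638, against 1.41% ± 0.397 in clonotypes not found in that spleen. The 2 sets differ in isotype, with on average 68.4% of shared and 19.1% of other clonotypes mostly IgA. Skin IgA clonotypes carried 3.47% mutation and skin IgM clonotypes 0.837%. Mutation was not compared within 1 isotype. Among the 69 skin clonotypes found in both technical libraries of a replicate, 50 were in the spleen of the same number.

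All 12 named largest skin clonotypes were mostly or wholly IgA, all 12 were found in the spleen of the same number and 0 in a spleen of another number. IGHV1-7 IGHJ3 AKYYSSWFAY (V gene, J gene and CDR3 amino acids) took 1783 copies, 23.8% of skin replicate 2, and had 2405 copies in spleen replicate 2 and 89 in lymph node replicate 2. IGHV5-6 IGHJ4 ARRTAMDY took 17.7% of the same skin replicate, with 191 copies in its spleen and 7 in its lymph node. IGHV14-3 IGHJ2 SIYYSFPFEY took 13.0% of skin replicate 1, with V mutation of 7.76% and 658 copies in its spleen. IGHV9-3 IGHJ1 ARGYYGTSHWYFDV took 14.6% of skin replicate 3 with V mutation of 0.0125%, and 119 copies in its spleen. IGHV14-1 IGHJ2 STGYYGQYYLAY took 12.3% of skin replicate 4, with 54.0% of its copies IgA and 20 copies in its spleen. IGHV1-42 IGHJ3 ARGDYDYDEFSY took 5.75% of that replicate, with 1842 copies in its spleen. Of the 12, 3 were found in the lymph node of the same number, among them IGHV1-53 IGHJ4 ARGHLLYAMDY, with 317 copies in skin replicate 3, 993 in its spleen and 685 in its lymph node. In lymph nodes of other numbers 2 of the 12 were found, AKYYSSWFAY with at most 1 copy and ARGHLLYAMDY with at most 6.

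The largest skin clonotypes shared with the lymph node of the same number included 2 of IgM in replicate 1. IGHV3-6 IGHJ2 ASYSNFDY had 17 skin, 123 spleen and 53 lymph node copies there, and up to 495 copies in a spleen of another number. IGHV11-2 IGHJ1 MRYGGYWYFDV, of a V gene on the B-1 list, had 14 skin, 4 spleen and 8 lymph node copies. In replicate 4 the largest was IGHV6-3 IGHJ4 TIYYDYDGGYPMDY, IgA, with 131 skin, 1388 spleen and 386 lymph node copies.

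**Figure D4:**
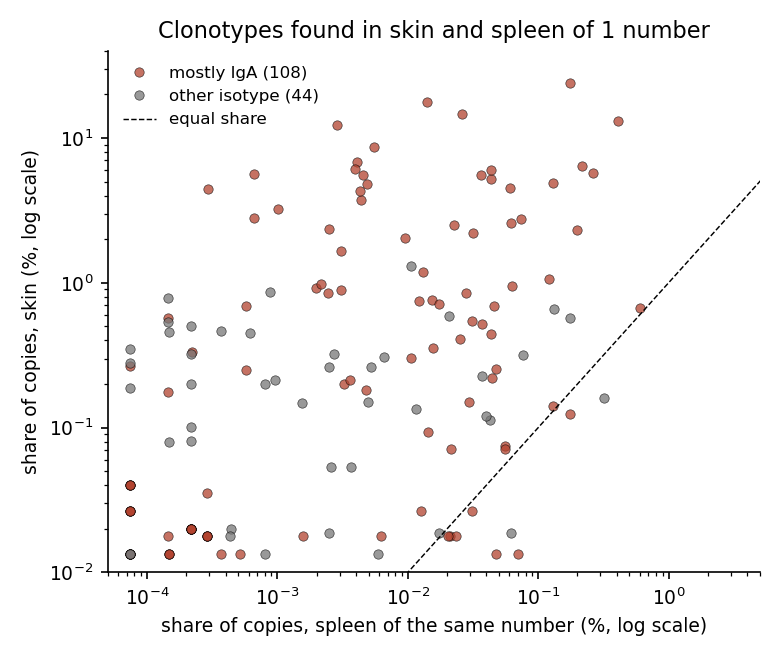
Share of copies (%, log axes) of the 152 skin clonotypes also found in the spleen of the same number, in spleen (horizontal) and skin (vertical). Points are clonotypes, 108 mostly IgA and 44 mostly of another isotype, and the dashed line marks equal shares.

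Repeat sampling of 1 replicate was incomplete in every tissue. Of the clonotypes of the smaller technical library, 12.1% ± 4.16 were found again in the other library in skin, 10.2% ± 2.79 in spleen and 9.31% ± 3.60 in lymph node (SD, n = 4). Clonotypes found in both libraries held 55.5% ± 12.3 of skin copies, 51.2% ± 12.4 of spleen copies and 29.8% ± 12.2 of lymph node copies. Absence of a clonotype from a tissue is therefore absence at this depth.

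Different skin replicates shared nothing with each other. Of 1096 skin clonotypes defined by V gene, J gene and CDR3 amino acids, 0 occurred in 2 or more skin replicates, and of 1267 by junction nucleotides also 0. At 239 clonotypes drawn per replicate, the mean share found in another replicate of the tissue was 0% in skin, 0% in spleen and 0.00139% in lymph node, with 0 of 3 comparisons past the threshold (lowest exact permutation p = 0.600, adjusted p = 1). Draws this small from the far larger spleen and lymph node sets leave almost no overlap whatever the sharing. The comparison therefore cannot tell whether tissues differ.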

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

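Of the tests in these paragraphs, those of skin copies assigned to spleen, of public rearrangements, of circulating cells, of equal numbers of all copies, of clonotypes counted once and of other splits of the samples were chosen only after the result was seen.

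In 81 groups of 4 replicates, 7 values stood apart from the other 3, where chance gives about 1 in 20 (4.05). Spleen replicate 1 had 3 of them: IgE at 0.746% of copies (others 0.000656% to 0.0131%), IgG1 at 3.41% (others 0.214% to 0.230%) and a mean CDR3 length of 12.12 amino acids (others 11.97 to 11.99). Its 1209 IgE copies fell in 148 clonotypes, the largest of which, IGHV1-5 IGHJ2 TKWGVTLDFDY, held 15.6% of them. In lymph node replicate 4 the 10 largest clonotypes took 22.8% of copies (others 6.68% to 8.56%), and IGHV9-3 IGHJ2 ARSEDLGYYVY, IgG2 with V mutation of 0%, alone took 9.32% of all its copies. Skin replicate 2 had IgG2 at 0.747% (others 0% to 0.0560%), with 35 of its 56 IgG2 copies in IGHV1-64 IGHJ4 ARGGVNYWYAMDY. Skin replicate 1 had IgG1 at 0.0187%, from 1 copy, where the others had 0. The B-1 and natural antibody list took 1.86% of clonotypes in skin replicate 3 (others 5.0% to 5.45%).

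Large IgA clonotypes of skin were found in the spleen of the same number. Spleen copies wrongly assigned to skin libraries would bring the largest spleen clonotypes along: of 73 spleen clonotypes that proportional spill-over would place at 10 or more skin copies, 1 was present (1.37%), which argues against this. Skin copies assigned to spleen libraries would leave fewer copies in spleen: of the 60 shared IgA clonotypes with 10 or more skin copies 26 (43.3%) had more copies in spleen, but 34 had fewer, among them 9 of the 12 largest. For those 34 such assignment would carry other isotypes along. The rate assumed was their median spleen to skin ratio in each replicate, 0.124 to 0.408. Of 208 skin clonotypes of other isotypes that it would bring to 3 or more spleen copies 18 were present (8.65%), which argues against assignment at that rate. Of the 208, 116 came from replicate 1, where the ratio rested on 5 clonotypes. Lower rates were not tested and stay open for clonotypes such as ARAPYGNYRFAY, with 464 skin and 9 spleen copies. Public rearrangements would also appear in other numbers, where the same-number excess was 11.1 percentage points. Circulating cells of the same clones in skin vessels cannot be told apart from resident cells, since no blood was analysed here. Skin clonotypes without IgA copies showed a same-number excess of 3.17 points (1.89 without replicate 2), with replicate 1 higher in spleen 2 (4.0%) than in its own (2.67%). Spleen 1 was sampled far less deeply than spleen 2, and these shares were not corrected for depth. The biological hypothesis that IgA clones were spread over skin and spleen of 1 animal stays open, and it assumes that a number is 1 mouse, which the labels do not state.

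More skin clonotypes were found in spleen than in lymph node of the same number. With spleen and lymph node drawn to 93191 copies each, spleen held 8.22% ± 3.08 and lymph node 2.17% ± 0.994 of skin clonotypes, a difference of 6.05 points (higher in 4 of 4 numbers; exact sign-flip permutation p = 0.125, the smallest for n = 4), which argues against depth as the whole cause. With IgA copies alone drawn to 1134 each, the shares of skin IgA clonotypes were 11.3% ± 3.39 and 4.14% ± 1.17, a difference of 7.13 points (4 of 4 numbers; exact permutation p = 0.125, n = 4), which argues against the low IgA content of lymph node as the whole cause. A tissue difference in where these clones reside may remain, and which lymph node was sampled is not given in the sources used here.

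The IgA share of copies was higher in skin than in spleen. If a few clonotypes with many copies each were the whole cause, counting each clonotype once would remove the excess. It left 17.8 percentage points (25.6% against 7.86%, exact permutation p = 0.0286, n = 4 against 4, adjusted p = 0.0667 over 7 isotypes). Depth was unequal in this count, with 275 to 350 clonotypes per skin replicate and 25645 to 438995 per spleen. Rare clonotypes seen only at greater depth can lower the IgA share of spleen, so the test cannot decide. The criterion was restated after this value was seen. Under the first, an adjusted p below 0.05, the explanation would have stayed. Under the second, an excess above 1 SD of skin values with unadjusted p below 0.05, it would not. Neither criterion allows for the unequal depth. A few clonotypes with many copies each therefore stay open as a cause. A higher share of IgA cells in skin, or more IgA transcript per cell there, also stay open and were not tested.

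For the V genes, the real grouping into skin and spleen called 7, and 1 of the 35 splits of those samples, the real one, called as many. The highest other called 3. No smaller share than 1 of 35 is possible here. Splits that mix tissues also put any tissue difference into their spread, which can lower their counts. Chance is therefore not excluded for that count. The splits also do not secure each of the 7: simulated counts gave 5 false calls in this comparison, and a fit of the 8 samples alone called 0. For skin and lymph node the real grouping called 0, a count that all 35 of 35 splits must reach (highest other 0), so the splits decide nothing there. For spleen and lymph node the real grouping called 20, reached by 1 of 35 splits, with 1 as the highest other, under the same limits of the splits.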

How the results depend on the processing

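Of the alternatives, those on IgA clonotypes, on clonotypes without IgA copies, on nucleotide definitions of public clonotypes and on shares below the zero-count limit were added after the data were seen. Outside the left-out replicates, 167 values stayed the same, 33 counts moved by over 1.5 times, 8 results became stronger and 8 weaker. Causes of the changes were not tested, except where fewer samples limit the test. Weighting by reads, filters on non-functional sequences and lineages for sharing between replicates were not run.

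Correlation of V gene deviations did not pair samples of the same number (-0.175 to 0.252, own number best in 6 of 12 tests). Clonotype sharing did follow the numbers. Of skin clonotypes, 12.3% were in the spleen of the same number and 1.23% in other spleens, with the own number highest in 4 of 4. The pairing therefore stays open. With the replicate block, V genes called were 1 for skin against spleen, 0 for skin against lymph node and 11 for spleen against lymph node; isotypes 1 (IgG3; IgA had p = 0.207, adjusted p = 0.320, exact permutation) and 3 for skin against spleen and lymph node; J genes 2 for spleen against lymph node, without IGHJ1 (exact permutation, adjusted p = 0.693); V families 1 for spleen against lymph node. In the same comparison the block gave differences of 24.97 points in class-switched share (exact permutation p = 0.133), 0.296 in V mutation (exact permutation p = 0.534) and -0.272 amino acids in CDR3 length (exact permutation p = 0.0154). Its permutations also move the third tissue, so its p does not rest on the 2 compared tissues alone. How far this moved each p was not tested.

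V genes in skin against spleen, skin against lymph node and spleen against lymph node: 48, 37 and 34 with DESeq2, and 13, 13 and 0 with copies per V gene. Skin against spleen gave 0 with 8 samples only, 3 with technical library 2 alone (0 of the 7) and 3 with lineages (all among the 7). Skin against lymph node gave 5 without TMM, 2 without the filter on rare V genes, 1 without single-copy clonotypes, 3 and 2 with technical library 1 and 2 alone, and 1 with IgM only. Spleen against lymph node gave 38 with 8 samples only. Of 19 alternatives, IGHV1-7, IGHV5-6, IGHV1-42 and IGHV1-19 were called higher in skin in 4, 6, 4 and 6, and IGHV1-75, IGHV1-76 and IGHV1-80 lower in 15, 13 and 16.

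Isotypes were 0 for skin against spleen and 0 for skin against lymph node with each clonotype counted once and with shares below the zero-count limit of skin set to that limit, and 0 for skin against spleen without single-copy clonotypes. Class-switched share, skin against spleen, passed with technical library 1 alone (23.5). V mutation, skin against spleen, passed with lineages (0.816) and IgM only (0.249); spleen against lymph node failed with IgM only (0.0903); with IgA of 2 or more copies, skin against lymph node (0.976) and spleen against lymph node (0.714) failed. CDR3 length differences passed without single-copy clonotypes (-0.355 for skin, -0.417 for spleen, each against lymph node) and with copies as weights (-0.556 and -0.294). J genes, spleen against lymph node, fell to 0 with copies as weights. Sharing with lineages gave 1.53 for skin with lymph node and 0.182 for lymph node with spleen, and 0.571 for skin with lymph node without IgA copies, all past no threshold. Overlap of technical libraries was 24.5%, 44.0% and 22.7% in skin, spleen and lymph node without single-copy clonotypes, and 20.2%, 20.8% and 20.3% with lineages.

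Leaving out each replicate gave, for skin against spleen, skin against lymph node and spleen against lymph node, V genes of 2 to 11, 0 to 6 and 6 to 31, and V mutation of 0.622 to 0.984, 0.918 to 1.28 and 0.200 to 0.350. Isotypes were 0 in every case for skin against spleen and 0 to 6 for skin against lymph node, class-switched share 14.1 to 24.6 for skin against spleen, and J genes 0 to 3 for spleen against lymph node. Sharing was 9.47 to 13.8 for skin with spleen, 0.968 to 2.15 for skin with lymph node and 1.84 to 2.79 for lymph node with spleen, where 3 numbers cannot give an exact permutation p under 0.167.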

Other observations

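Of the tests here, sharing split by IgA was chosen after the data were seen; the criteria for the other 2 were written before their values were computed. Among lymph node clonotypes with IgA copies, the share found in the spleen of the same number exceeded that in other spleens by 34.1 percentage points, against 2.06 points for lymph node clonotypes without IgA copies (each exact one-sided permutation p = 0.0417, n = 4). Lymph node replicate 1 went the other way, with 17.0% of its IgA clonotypes in spleen replicate 1 and 23.3% in spleen replicate 2. Spleen replicate 1 held 25645 clonotypes and spleen replicate 2 438995, and these shares were not corrected for that depth. The corresponding values for skin were 31.1 and 3.17 points, the latter 1.89 without replicate 2 and with skin replicate 1 higher in spleen 2 (4.0%) than in its own (2.67%). The difference between IgA and other clonotypes was not itself tested.

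Sequence variants of shared IgA clonotypes were compared between tissues, for clonotypes with at least 5 IgA copies on each side. The most frequent full sequence in skin was also the most frequent in the spleen of the same number for 28 of 55 clonotypes (50.9%). Between the 2 technical libraries of a spleen the top sequence was the same in 53 of 67 (79.1%), and between the 2 of a skin sample in 29 of 36 (80.6%). The difference of 28.2 percentage points between the first and the second of these values exceeded the 20 points set before the test. It came from replicates 3 (9 of 18 against 16 of 18) and 4 (8 of 20 against 21 of 27), while replicate 1 had 4 of 6 in both and replicate 2 had 7 of 11 against 12 of 16. Among the 53 clonotypes in both comparisons the values were 49.1% and 81.1%. The skin top sequence was present at some level in spleen for 78.2%. As a hypothesis, members of these IgA clones may have diverged between skin and spleen; uneven sampling of few cells per clone in each tissue piece would give the same picture, since technical libraries of 1 RNA share their cells, and was not tested.

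A second hypothesis, that IgA clonotypes of skin carry a higher ratio of replacement to silent V mutations than those of spleen, gave no difference beyond the spread. The ratio was 2.58 ± 0.767 in skin, 2.52 ± 0.215 in spleen and 2.33 ± 0.142 in lymph node (SD, n = 4). The difference between skin and spleen was 0.0553 (exact permutation p = 0.857, adjusted p = 0.857), and the spread of skin leaves a moderate difference open.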
